A study of Mus musculus with 22 samples.

How the data were processed

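The series holds 22 libraries of polyadenylated RNA from mouse B16-F10 melanoma cells and OT-I CD8+ T cells, in 11 groups of 2. Per the series design, cells were sorted by flow cytometry with an antibody to EpCAM for cancer cells and to CD8 for T cells. The single-cell part of the study and the ovalbumin and GCaMP6s transgenes were not analysed here. Reads were aligned with HISAT2 to the mm10 genome build and counted per gene with featureCounts, per the submitters' processing notes, and their versions are not given in the sources used here. The authors deposited 1 table of RPKM values for 35976 genes in the 22 libraries, and all of its value columns were used. The kit marks the second strand, per the labels' protocol, but the strand setting of the counting is not given in the sources used here, so overlapping and antisense genes, among them small RNA genes inside host genes, cannot be told apart with certainty. Near-identical copies (class I genes, granzymes, Tgtp1 and Tgtp2, the Gbp and Ifit families, Gapdh and its pseudogenes) are uncertain because their reads can be placed on more than 1 of them.

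RPKM values were whole multiples of the value of 1 read for 100% of the 25630 genes above 0 (tolerance 0.0002 of a read), which gave the reads behind each value and the depth: 29.32 to 36.7 M assigned reads in T cell libraries and 31.82 to 37.0 M in B16 libraries. Replicates correlated at r = 0.9972 to 0.9984 across genes, no pair was identical, and chi-square over degrees of freedom between replicates ran from 4.41 to 16.64, so that all pairs differed by more than counting noise. The pairs furthest apart were T cells with B16-OVA at 6 h (16.64) and B16-WT at 6 h (15.82). The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Time and sequencing batch cannot be separated, since no batch is given in the labels.

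Groups were taken from the treatment labels for T cells and from the titles for B16 cells. The comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Each cell type was fitted apart, with 10 T cell and 12 B16 libraries, all groups sharing 1 estimate of the spread: limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) with a mean-variance trend, over genes at RPKM 1 or more in at least 2 libraries (11066 genes in T cells, 11611 in B16). The fold change on this scale understates that of low genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. T cells with B16-OVA were compared with T cells with B16-WT at 6 and 12 h, with a test of the change of that difference, and T cells with B16-WT with T cells at 0 h. B16-OVA was compared with B16-WT at each time and each line with its 0 h, with tests of the difference of the changes. Comparisons that share libraries are not independent; the antigen effects at 6 and 12 h share none.

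Gene lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, with p adjusted over all lists and comparisons of a cell type. Lists with fewer than 5 measured members were not tested. For T cells these were T cell receptor induced activation, cytokines and chemokines, cytotoxic effectors, inhibitory receptors, naive and memory genes, chemokine receptors and adhesion, and interferon response. For B16 they were interferon-gamma and type I interferon responses, class I and class II presentation, checkpoint ligands, NF-kB and TNF response, p53 and cell death, melanocyte differentiation, and dedifferentiation. Both cell types had actin and motility, S phase, mitotic (G2/M), glycolysis and hypoxia, cholesterol biosynthesis, unfolded protein and integrated stress response, and heat shock and dissociation stress lists. Of 70 list tests in T cells 44 passed, and 7 with an estimated correlation; of 135 in B16 cells 88 and 55 passed. The median, the mean and the test of a list differed in sign in 6 T cell and 12 B16 tests, of which 0 passed the threshold. Marker lists of T cells, melanoma cells, B cells, myeloid, natural killer, CD4+ and regulatory T cells, erythroid cells and mitochondrial transcripts were counted, not tested.

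Named genes are fixed anchors (Ifng, Gzmb, Nr4a1, Tnfrsf9 and Pdcd1 in T cells; Cd274, H2-K1, B2m, Cxcl10, Pmel and Mki67 in B16), and up to 5 genes per direction and comparison with the largest change past the threshold, a mean RPKM of at least 5 in the higher group and replicates that do not overlap. Clone names and genes 10 times higher in the other cell type at 0 h were left out of these. Up to 3 members of each list in the comparisons of B16-OVA with B16-WT, and the 3 most abundant members of each marker list, were added. Some genes that these rules name are not reported here. The share of the other cell type is the median over its markers (RPKM 5 or more there) of a library's RPKM as percent of that cell type in the same co-culture and time, or of all its 0 h libraries at 0 h. Alternatives were a pseudocount of 0.1, no filter, a filter at RPKM 5, median-of-ratios scaling, the replicate number as a block, only the groups compared, no variance trend, subtraction of the other cell type's RNA, leaving out genes abundant in the other cell type, and leaving out each library in turn. Limma's voom on the recovered reads was added after the data were seen. Where a left-out library leaves 1 in its group, that one is assumed to vary like the other groups.

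The procedure was tested on simulated reads, drawn with the mean levels of these libraries and 200 changed genes per comparison. Their spread was averaged over genes of like level after the most variable were left out, and all groups shared it. The data held more variable genes and far more calls, and no comparison of 6 h alone was simulated. The error rates below may therefore not hold for the data. For T cells with B16-OVA against B16-WT at 12 h (11066 genes) 65.7% of genes changed 1.5-fold were recovered, 92.5% of those changed 2-fold and 93.9% of those changed 4-fold, with 8 false calls (4.5% of calls). For the antigen effect at 12 h against 6 h the shares were 49.3, 73.1 and 92.4%, with 1 false call (0.7%). For B16-OVA against B16-WT at 12 h (11611 genes) they were 80.6, 94 and 97%, with 12 false calls (6.2%), and for the difference of the 12 h changes 64.2, 77.6 and 92.4%, with 3 false calls (1.9%). Raised lists gave camera p of 1.1e-87, 2.7e-77, 2.8e-92 and 1.1e-82 in these 4 simulations, and unchanged lists 0.79, 0.39, 0.78 and 0.45. Positions come from the RefSeq annotation of GRCm38.p6, the assembly of mm10, matched by symbol for 12108 of 12769 tested genes (94.8%). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, sums and plots.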

Results

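RNA was sequenced from mouse melanoma cells and CD8+ T cells at 0, 6 and 12 h of a co-culture series on T cell motility and on the interaction of cancer cells with T cells. The cancer cells were B16-F10, a melanoma line from C57BL/6 mice, either unmodified (B16-WT) or made by lentiviral transfer to carry ovalbumin and the calcium sensor GCaMP6s (B16-OVA). The T cells were OT-I cells from spleen, whose transgenic receptor recognises an ovalbumin peptide presented by the class I molecule that H2-K1 encodes, and they had been activated with beads that carry antibodies to CD3 and CD28. The 11 groups of 2 libraries were T cells at 0 h, T cells with B16-WT and with B16-OVA at 6 h and at 12 h, and each B16 line at 0, 6 and 12 h. The series design places the bulk libraries in the co-culture, whereas the labels of the B16 libraries name no treatment. Each library held 29.32 to 37.0 M reads assigned to genes, and the 10 highest genes took 5.29 to 6.64% of them. Between 10343 and 10524 genes reached RPKM 1 in the T cell libraries and between 10587 and 10964 in the B16 libraries. Levels are given in RPKM as mean ± SD (n = 2), and changes as log2(RPKM + 1) differences ± SE with limma adjusted p. For gene lists that passed the camera test, counts adjusted over the list alone are given where they differed from those over all genes.

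Each sorted population carried a small amount of the other cell type's RNA, which differed between groups. The median T cell marker in the B16 libraries stood at 0.02 ± 0.029% of its T cell level in B16-WT at 0 h, 1.457 ± 0.176% at 6 h and 1.932 ± 0.084% at 12 h (SD, n = 2). In B16-OVA it was listed at 0 in both libraries at 0 h and stood at 3.375 ± 0.053% at 6 h and 1.797 ± 0.209% at 12 h. Melanoma markers in the T cell libraries stood at 0.005 ± 0.005% of their B16 level at 0 h. They reached 0.58 ± 0.076% and 1.34 ± 0.118% in T cells with B16-WT at 6 and 12 h, and 0.30 ± 0.028% and 1.386 ± 0.266% in T cells with B16-OVA. With the mean over markers in place of the median, the shares were 0.489% in T cells at 0 h, 0.98% and 0.764% in T cells with B16-WT and with B16-OVA at 6 h, and 0.054% and 0.040% in B16-WT and B16-OVA at 0 h. Among the T cell markers, Thy1, Coro1a and Gzmb were the most abundant in T cells, and Pmel, Tyrp1 and Dct led the melanoma markers in B16. All 17 measured T cell markers rose in both B16 lines at 6 and 12 h against 0 h, and 16 of 17 were higher in B16-OVA than in B16-WT at 6 h. Of 11 melanoma markers measured in T cells, 9 rose at 6 h and 11 at 12 h of co-culture with B16-WT, and 6 were lower with B16-OVA than with B16-WT at 6 h. Other lineages left little signal: 1 B cell marker (Cd79b), 1 myeloid marker (Cd68) and 2 natural killer cell markers (Eomes and Gzma, both also expressed by activated CD8+ T cells) were measured in T cells, and no erythroid marker reached the filter. Cd79b fell in T cells with B16-WT from 6.01 RPKM at 0 h to 3.79 at 12 h, while Cd68 rose from 3.78 to 5.13. In B16 cells Cd68 and Gzma were the only measured members of the myeloid and natural killer lists, and no B cell marker passed the filter. Of the markers of CD4+ and regulatory T cells, 5 were measured in T cells, and 2 rose and 2 fell in T cells with B16-WT at 12 h against 0 h.

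T cells with B16-OVA were compared with T cells with B16-WT. The difference is called the antigen effect here, but it cannot be told from effects of other differences between the lines, which differed in 5040 genes at 0 h. At 6 h, interferon-inducible genes and 7 of 16 cytokine and chemokine genes were higher in T cells with B16-OVA, and genes of DNA replication were lower. Xcl1, a chemokine that attracts cross-presenting dendritic cells, stood at 58.4 ± 10.2 RPKM against 4.89 ± 1.19 (log2 change 3.34 ± 0.15, adjusted p = 2.59e-06). Ccl1 stood at 5.22 ± 1.75 against 0.0575 ± 0.0813 (2.53 ± 0.21, adjusted p = 0.000204). Ifng, the main effector cytokine of CD8+ T cells (chromosome 10, 118441046 to 118445894, GRCm38.p6), stood at 15.6 ± 4.29 against 3.83 ± 0.773 RPKM (1.77 ± 0.20, adjusted p = 0.00104). Iigp1 and Gbp2, interferon-inducible GTPases of defence against intracellular pathogens, rose by 3.12 ± 0.12 (adjusted p = 7.42e-07) and 2.16 ± 0.05 (adjusted p = 7.38e-08). Gzmb, the protease granzyme B of cytotoxic granules, was lower, at 453 ± 16.9 against 686 ± 17.9 RPKM (-0.60 ± 0.04, adjusted p = 8.9e-05).

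By group at 6 h, 20 of 25 measured interferon response genes were higher and 0 lower (21 and 2 when adjusted over the list alone; camera adjusted p = 5.5e-17, and 0.011 with an estimated correlation), among them Gbp6 (2.21). The cytokine and chemokine list had 7 of 16 members higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 2.1e-05), including Ccl3 (1.84), and its adjusted p = 0.11 with an estimated correlation. Of 26 genes induced by T cell receptor signalling, 12 were higher and 3 lower, led by Egr3 (1.12), the costimulatory receptor Tnfrsf4 (1.07) and Tnfrsf9, which encodes 4-1BB (0.93, adjusted p = 0.000176). Nr4a1 did not pass (0.01, adjusted p = 0.975). That list passed at adjusted p = 0.015, with adjusted p = 0.2 with an estimated correlation. Inhibitory receptors had 4 of 12 members higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.069 with an estimated correlation). Pdcd1, the gene of PD-1, rose by 0.71 (adjusted p = 0.00059), Tigit by 0.76 and Lag3 by 0.55. Naive and memory genes had 8 of 16 members higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0046, and 0.13 with an estimated correlation). Il7r was at 0.63 and Bach2 at 0.58. Cholesterol biosynthesis had 8 of 20 members higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.015, and 0.1 with an estimated correlation). Msmo1 was at 0.67, Insig1 at 0.64 and Sc5d at 0.52.

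Replication genes of S phase were lower in 20 of 22 cases and higher in 0 (22 lower adjusted over the list alone; adjusted p = 1.7e-14, and 0.02 with an estimated correlation). The amounts were small, such as -0.33 for Mcm2 and for Chaf1b and -0.43 for E2f1. With only the groups compared E2f1 lost its call. Heat shock and dissociation stress genes had 9 of 14 lower and 0 higher (12 lower adjusted over the list alone; adjusted p = 2.4e-10, and 0.02 with an estimated correlation), including Fosb (-0.67), Hsph1 (-0.63) and Junb (-0.54). Mitotic genes had 5 of 22 lower (8 adjusted over the list alone; adjusted p = 0.0017, and 0.1 with an estimated correlation). Cdk1 was at -0.30, Kif23 at -0.26 and Mki67 at -0.22. With only the groups compared these lost their calls, as did Cdk1 and Mki67 without the filter and Mki67 without the variance trend. Unfolded protein and integrated stress response genes had 10 of 20 lower (10 adjusted over the list alone; adjusted p = 3.2e-05, and 0.069 with an estimated correlation). Sdf2l1 was at -0.43 and Hsp90b1 and Creld2 both at -0.38. Glycolysis and hypoxia genes had 9 of 22 lower and 1 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0015, and 0.31 with an estimated correlation). Ndrg1 was at -0.44 and the lactate exporter Slc16a3 at -0.37 while Egln3 rose by 0.78. Both falls lost their calls with only the groups compared, and that of Ndrg1 also without the filter. Actin and motility genes had 9 of 43 lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.0025, and 0.29 with an estimated correlation). Pfn1 was at -0.33, Stmn1 at -0.30 and Arhgap15 at 0.28. These calls were lost without the filter and with only the groups compared. Arhgap15 also lost its call with median-of-ratios scaling (0.25), without the variance trend and with B16 RNA subtracted (0.27 each). The cytotoxic effector list (5 higher and 2 lower of 19, adjusted p = 0.4) and the chemokine receptor and adhesion list (4 higher and 3 lower of 22, adjusted p = 0.82) did not pass. Among their members the receptors Klrk1 (0.99), Klrd1 (0.81), Ccr8 (1.10) and Ccr4 (0.78) rose. The largest falls outside the lists were those of Cdh1 (-0.98), Ggt1 (-0.91), Sik1 (-0.73), Fosl2 (-0.72) and Drc1 (-0.68). Gapdh differed by 2.45 ± 0.53 (adjusted p = 0.0182), but its libraries spread widely at 56.7 ± 26.1 RPKM with B16-OVA, and reads may be shared with its many pseudogenes. Without the filter Gapdh lost its call.

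In all, 911 genes were higher and 634 lower at 6 h, of which 35 and 9 changed at least 2-fold. This count depended on single libraries: it was 395 without T with B16-WT 6h replicate 2, 498 without T with B16-WT 6h replicate 1, 2527 without T with B16-OVA 6h replicate 2, 327 with only the groups compared in the fit and 939 without the filter on low values. Leaving out T with B16-WT 6h replicate 1 or replicate 2 ended the calls of Gapdh (2.41 and 2.49), Pfn1 (-0.32 and -0.34), Stmn1 (-0.28 and -0.33), Arhgap15 (0.29 and 0.26), Cdk1 (both -0.30), Kif23 (-0.23 and -0.29), Mki67 (-0.23 and -0.21), Ndrg1 (both -0.44) and Slc16a3 (-0.42 and -0.33), and leaving out replicate 2 also those of E2f1 (-0.37), Sc5d (0.50) and the T cell receptor list (adjusted p = 0.054). Leaving out T with B16-OVA 6h replicate 2 ended the calls of Gapdh (1.97) and Mki67 (-0.17) and of the T cell receptor, naive and memory and cholesterol lists (adjusted p = 0.13 for each), and leaving out replicate 1 those of Stmn1 (-0.20), Arhgap15 (0.17) and the actin list (adjusted p = 0.08).

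At 12 h the difference between T cells with B16-OVA and with B16-WT was larger and centred on the same chemokines, on Ifng and on interferon-inducible genes, while mitotic genes were lower. Ifng reached 127 ± 2.54 RPKM with B16-OVA against 12.7 ± 1.09 with B16-WT (3.23 ± 0.20, adjusted p = 7.37e-06), and Xcl1 250 ± 4.29 against 9.39 ± 0.38 (4.59 ± 0.15, adjusted p = 1.37e-07). Ccl3 and Ccl4, inflammatory chemokines, reached 46.5 ± 3.28 and 45.3 ± 0.0225 RPKM against 2.06 ± 0.234 and 2.58 ± 0.376 (3.95 ± 0.17 and 3.70 ± 0.16, adjusted p = 8.39e-07 for both). Ccl1 reached 47.1 ± 2.79 against 1.61 ± 0.165 (4.20 ± 0.21, adjusted p = 2.09e-06). Egr1, an immediate early transcription factor downstream of ERK (chromosome 18, 34861207 to 34864956, GRCm38.p6), stood at 78.3 ± 3.42 against 14.6 ± 0.0494 (2.35 ± 0.10, adjusted p = 8.39e-07). Aurka, a kinase of the mitotic spindle, fell to 32.2 ± 1.26 from 76.2 ± 0.131 RPKM (-1.22 ± 0.06, adjusted p = 1.73e-06).

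By group at 12 h, 14 of 16 cytokine and chemokine genes were higher and 0 lower (adjusted p = 8.8e-11, and 0.058 with an estimated correlation). The B16 share of 1.386% in the T cell libraries with B16-OVA may add to genes that B16-OVA cells induced. Cxcl10, a list member, was at 1620 RPKM in B16-OVA against 47.0 in B16-WT, and interferon-inducible genes may be raised likewise. Of 26 genes induced by T cell receptor signalling, 19 were higher and 2 lower (adjusted p = 3.7e-08, and 0.057 with an estimated correlation). Egr3 rose by 2.79, Crtam by 1.71 and Tnfrsf9 by 0.38 (adjusted p = 0.00407), while Nr4a1 did not pass (0.15, adjusted p = 0.248). The interferon response list had 23 of 25 members higher and 0 lower (adjusted p = 2.5e-17, and 0.011 with an estimated correlation). Iigp1 was at 3.67, Gbp2 at 2.90 and Gbp6 at 2.35. The cytotoxic effector list went both ways, with 8 of 19 higher and 5 lower (adjusted p = 0.54). Klrk1 (1.38) and Tbx21, which encodes the effector transcription factor T-bet (1.37), rose, while Gzmc (-1.70) and Gzmb (-0.31, adjusted p = 0.000578) fell. Inhibitory receptors had 7 of 12 higher and 2 lower (adjusted p = 0.023, and 0.11 with an estimated correlation). Il10ra was at 1.15, Eomes at 0.92, Lag3 at 0.83 and Pdcd1 at 0.43 (adjusted p = 0.00173). Cholesterol biosynthesis had 7 of 20 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.036, and 0.12 with an estimated correlation). Fdps was at 0.65, Idi1 at 0.62 and Cyp51 at 0.54.

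Mitotic genes were lower in 21 of 22 cases and higher in 0 (22 lower adjusted over the list alone; adjusted p = 4.6e-14, and 0.02 with an estimated correlation). Nusap1 was at -1.03 and Kif23 at -0.99. Of 22 S phase genes 12 were lower and 1 higher (adjusted p = 0.0032, and 0.11 with an estimated correlation), with Cdt1 at -0.43, Tyms at -0.40 and Rrm2 at -0.31. Naive and memory genes had 9 of 16 lower and 3 higher (10 and 3 adjusted over the list alone; adjusted p = 0.025, and 0.2 with an estimated correlation). S1pr1, the receptor for lymphocyte egress, was at -1.0, its regulator Klf2 at -0.73 and Lef1 at -0.72. Actin and motility genes had 13 of 43 lower and 5 higher (adjusted p = 0.039, and 0.48 with an estimated correlation). S100a4 was at -1.25, Stmn1 at -0.68 and Myo1f at -0.64. In the chemokine receptor and adhesion list, 11 of 22 were lower and 7 higher (12 and 7 adjusted over the list alone; adjusted p = 0.19). Ccr2 was at -1.0, Cxcr4 at -0.80 and Ccr8 at 1.59. The glycolysis and hypoxia list (3 higher and 6 lower of 22, adjusted p = 0.54), the unfolded protein and integrated stress response list (7 higher and 5 lower of 20, adjusted p = 0.83) and the heat shock list (3 higher and 6 lower of 14, adjusted p = 0.41) did not pass. In them Egln3 (0.80), Pfkp (0.39) and Hspd1 (0.41) rose and Ndrg1 (-0.74), Ddit3 (-1.04), Ddit4 (-0.93), Trib3 (-0.81), Fos (-0.57) and Btg2 (-0.42) fell. Other large falls were those of Cenpl (-1.78), Ifitm1 (-1.60), Sgol2a (-1.55) and Ccng2 (-1.42).

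In all, 2146 genes were higher and 1946 lower at 12 h, 133 and 46 of them at least 2-fold. Of 13 mitochondrially encoded transcripts 5 were higher and 0 lower (median 0.29). The count was 2651 without T with B16-OVA 12h replicate 1 and 2719 without its replicate 2. Leaving out replicate 1 ended the calls of Btg2 (-0.33), the actin list (adjusted p = 0.059) and the cholesterol list (adjusted p = 0.055), as did T with B16-WT 12h replicate 1 for the actin list (adjusted p = 0.083) and replicate 2 for the cholesterol list (adjusted p = 0.076).

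**Figure D1:**
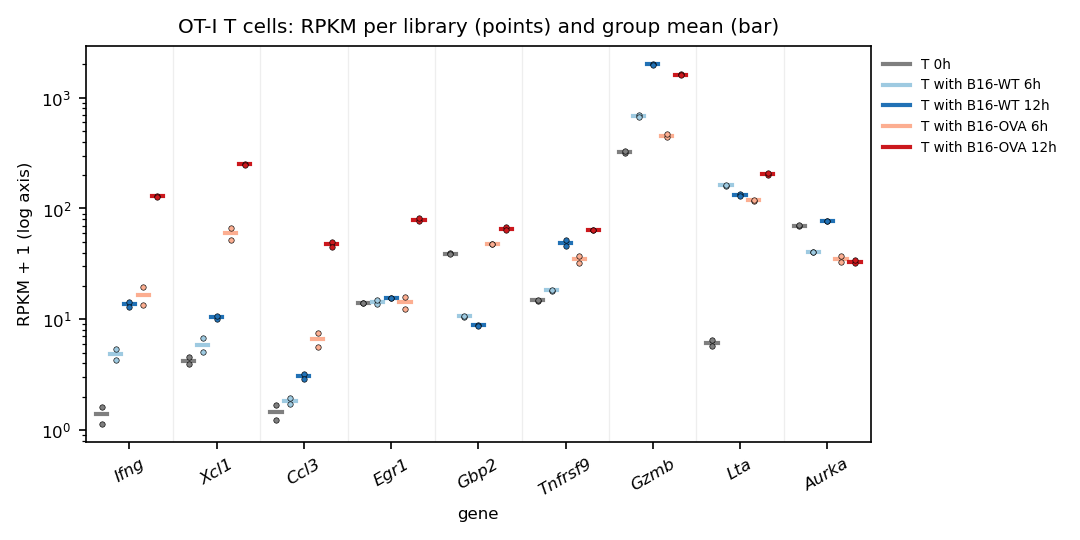
RPKM + 1 on a log axis for 9 genes in OT-I T cells at 0 h and with B16-WT or B16-OVA at 6 and 12 h; points are single libraries and bars group means (n = 2). Ifng reached 127 RPKM with B16-OVA at 12 h against 12.7 with B16-WT, and Lta was at 5.11 RPKM at 0 h and 131 with B16-WT at 12 h.

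The antigen effect, the difference between T cells with B16-OVA and with B16-WT, itself changed from 6 h to 12 h. It grew for Egr1 (2.37 ± 0.14, adjusted p = 5.47e-05), for the cytokine Il3 (2.34 ± 0.16, adjusted p = 8.45e-05), Ccl3 (2.12 ± 0.24, adjusted p = 0.000613) and Ifng (1.47 ± 0.28, adjusted p = 0.00675). It moved down for Tnfrsf9 (-0.55 ± 0.11, adjusted p = 0.0069), Gzmc (-1.63 ± 0.18, adjusted p = 0.000591), the centromere gene Cenpl (-1.59 ± 0.12, adjusted p = 0.000121), Ccng2 (-1.45 ± 0.07, adjusted p = 4.56e-05) and Sgol2a (-1.39 ± 0.13, adjusted p = 0.000244). Gzmb moved up (0.29 ± 0.06, adjusted p = 0.0102). Pdcd1 (-0.28, adjusted p = 0.0873) and Nr4a1 (0.15, adjusted p = 0.48) did not pass, but Pdcd1 did without T with B16-OVA 6h replicate 1 (-0.37) and Nr4a1 without its replicate 2 (0.32). Mitotic genes moved down in 19 of 22 cases and up in 0 (20 down adjusted over the list alone; adjusted p = 3.7e-11, and 0.02 with an estimated correlation). Cytokines moved up in 12 of 16 cases (13 adjusted over the list alone; adjusted p = 5.7e-09, and 0.069 with an estimated correlation). Genes induced by T cell receptor signalling moved up in 16 of 26 cases and down in 3 (17 and 4 adjusted over the list alone; adjusted p = 6e-07, and 0.058 with an estimated correlation). Naive and memory genes moved down in 11 of 16 cases and up in 1 (11 and 3 adjusted over the list alone; adjusted p = 0.00034, and 0.087 with an estimated correlation). Of the genes tested, 1196 moved up and 1326 down, or 1271 and 1193 with median-of-ratios scaling. The antigen effects at both times shared 377 higher genes, against 176.7 for independent lists, and 266 lower genes, against 111.5. Another 207 were called in opposite directions. No value for independent lists was computed, so no excess is shown. Across the 11066 genes, which are not independent replicates, Pearson's r was 0.355 and Spearman's rho 0.221. The 2522 calls numbered 1502 and 1581 without T with B16-WT 6h replicates 2 and 1, and 1574 and 1540 without T with B16-OVA 12h replicates 1 and 2. Without T with B16-WT 12h replicate 2 the 1326 that moved down numbered 864. Ifng did not pass with a pseudocount of 0.1 (1.34). Shared counts were 163 higher and 64 lower without T with B16-WT 6h replicate 2, and 180 and 86 without its replicate 1. With only the groups compared they were 144 and 47.

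T cells in co-culture with B16-WT were also compared with T cells at 0 h. Lta, the gene of lymphotoxin alpha, rose from 5.11 ± 0.489 RPKM to 161 ± 2.16 at 6 h (4.74 ± 0.06, adjusted p = 8.66e-11) and was at 131 ± 4.33 at 12 h. Cdh1, which encodes E-cadherin, rose from 0.013 ± 0.000367 to 20 ± 0.123 and 29.4 ± 0.0944 RPKM. Gzmb rose from 320 ± 8.35 to 686 ± 17.9 (1.09 ± 0.04, adjusted p = 1.09e-07) and 1992 ± 56.3 (2.63 ± 0.04, adjusted p = 3.4e-10). Other large rises were those of Cish (3.97), Rgs1 (3.75) and Bhlhe40 (3.71) at 6 h, and of Ifitm1 (5.25), Bhlhe40 (4.38) and Nfkbia (4.15) at 12 h. Arl4d (-3.57 and -3.46) and Gucy2e (-2.49 and -2.88) fell at both times, Irgm2 (-2.81) and Iigp1 (-2.40) were among the largest falls at 6 h, and Dapl1 (-2.79) and Tspan32 (-2.78) among those at 12 h. Gapdh was lower at 6 h (-2.99 ± 0.53, adjusted p = 0.00121), from a widely spread 84.8 ± 44.7 RPKM at 0 h. Ifng rose by 1.82 ± 0.20 and 3.32 ± 0.20 from 0.385 ± 0.346 RPKM, and Tnfrsf9 by 0.31 and 1.73. Pdcd1 fell by 0.70 and 0.45, while Nr4a1 rose at 12 h (1.28, adjusted p = 5.81e-06) but did not pass at 6 h (-0.07, adjusted p = 0.561).

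Of 20 cholesterol biosynthesis genes, 19 were lower and 1 higher at 12 h (adjusted p = 1.1e-07, and 0.02 with an estimated correlation). At 6 h 9 were lower and 5 higher and the list did not pass (adjusted p = 0.42). Naive and memory genes were lower in 11 of 16 cases at 6 h and 12 of 16 at 12 h, with 2 and 3 higher (adjusted p = 0.0021 and 0.0025, and 0.11 with an estimated correlation at both times). Glycolysis and hypoxia genes were lower in 16 and 15 of 22 cases and higher in 3 and 2 (adjusted p = 0.00073 and 0.0028, and 0.29 and 0.35 with an estimated correlation). Unfolded protein and integrated stress response genes were higher in 15 and 14 of 20 cases and lower in 3 at each time (adjusted p = 3.7e-06 and 0.00029, and 0.059 and 0.085 with an estimated correlation). Heat shock and dissociation stress genes were higher in 10 of 14 cases and lower in 1 at each time (adjusted p = 8.3e-05 and 0.00073, and 0.061 and 0.081 with an estimated correlation). Without ovalbumin, genes induced by T cell receptor signalling were higher in 14 and 15 of 26 cases and lower in 5 and 8 (14 and 16 higher adjusted over the list alone; adjusted p = 0.0013 and 0.009, and 0.11 and 0.17 with an estimated correlation). Cytokines and chemokines were higher in 6 and 10 of 16 cases and lower in 1 and 2 (adjusted p = 0.036 and 0.0022, and 0.36 and 0.2 with an estimated correlation). The 6 h call was lost with median-of-ratios scaling (0.06) and without T with B16-WT 6h replicate 2 (0.053). Mitotic genes were lower in 19 of 22 cases at 6 h (adjusted p = 2.4e-06, and 0.057 with an estimated correlation), and the list did not pass at 12 h (3 higher and 9 lower, adjusted p = 0.48). Interferon response genes were lower in 15 of 25 cases and higher in 4 at 6 h (adjusted p = 0.0026, and 0.082 with an estimated correlation), and the list did not pass at 12 h (adjusted p = 0.072) except with median-of-ratios scaling (0.043). At 6 h 2641 genes were higher and 3436 lower, and at 12 h 3035 and 3690. With median-of-ratios scaling the numbers were 2958 and 3088 at 6 h and 3381 and 3338 at 12 h. The median melanoma marker rose by 1.12 and 1.81 in these comparisons, and time in co-culture cannot be separated here from contact with B16 cells, since T cells alone were sampled at 0 h only.

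B16-OVA and B16-WT cells were compared at 0 h to find how the lines differed before T cells acted on them. H2-K1, the class I heavy chain that presents the ovalbumin peptide to OT-I cells (chromosome 17, 33996012 to 34000619, GRCm38.p6), was lower in B16-OVA, at 1.54 ± 0.174 against 11.8 ± 0.00255 RPKM (-2.34 ± 0.07, adjusted p = 1.05e-08). H2-D1 was lower as well (-0.75), and both may share reads with near-identical class I genes. Prg4, which encodes lubricin, stood at 0.0201 ± 0.000342 against 22.8 ± 1.07 RPKM (-4.54 ± 0.06, adjusted p = 3.54e-11). The pigmentation genes Oca2 (-2.67 ± 0.07, adjusted p = 4.03e-09) and Trpm1 (-1.90 ± 0.05, adjusted p = 3.71e-09) were lower. Isyna1, of inositol synthesis, stood at 18.6 ± 0.599 against 0.252 ± 0.0987 RPKM (3.97 ± 0.09, adjusted p = 1.75e-09). The lysosomal channel gene Mcoln3 stood at 9.35 ± 0.157 RPKM in B16-OVA while listed at 0 in both B16-WT libraries. Cbr3 (3.09), Rgs2 (2.98) and Mgarp (2.94) were also higher, and Gpr137c (-3.67), Hgsnat (-2.58) and Ddah2 (-2.05) lower. Cxcl10 differed by -1.63 (adjusted p = 2.74e-07) and Mki67 by -0.41 (adjusted p = 3.81e-05). Cd274 (0.30, adjusted p = 0.0929), B2m (0.07, adjusted p = 0.478) and Pmel (-0.02, adjusted p = 0.675) did not pass.

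Cholesterol biosynthesis genes were higher in B16-OVA at 0 h in 14 of 20 cases and lower in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.00066, and 0.027 with an estimated correlation). Sqle was at 0.69 and Hmgcs1 at 0.53 but Acat2 at -0.56. Actin and motility genes were lower in 20 of 39 cases and higher in 5 (25 and 6 adjusted over the list alone; adjusted p = 0.00047, and 0.06 with an estimated correlation), including Ezr (-0.88), Vasp (-0.84) and Vcl (-0.80). Mitotic genes were higher in 12 of 22 cases and lower in 2 (adjusted p = 0.0044, and 0.14 with an estimated correlation). Nusap1 was at 0.62, Bub1b at 0.57 and Aurka at 0.53. S phase genes were lower in 10 of 22 cases and higher in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.032, and 0.087 with an estimated correlation). Uhrf1 was at -0.39, Rrm1 at -0.36 and Lig1 at -0.34. Melanocyte differentiation genes were lower in 9 of 22 cases and higher in 2 (adjusted p = 0.037, and 0.089 with an estimated correlation). Slc24a5 was at 0.74. Class I presentation genes were lower in 8 of 21 cases and higher in 2 (adjusted p = 0.046, and 0.17 with an estimated correlation). Psme2 was at 0.87. Neither interferon list passed. Of the interferon-gamma list 4 of 30 were higher and 1 lower (adjusted p = 0.69), with Irgm1 at 0.65 and Irgm2 at 0.27. Of the type I list 2 of 23 were higher and 5 lower (adjusted p = 0.58), with Rsad2 at 0.49, Xaf1 at 0.31 and Ifit3 at -0.30. Nor did the checkpoint ligand (adjusted p = 0.52), NF-kB and TNF (0.99), p53 and cell death (0.17), dedifferentiation and mesenchymal (0.22), glycolysis and hypoxia (0.4), unfolded protein and integrated stress response (0.44) and heat shock (0.19) lists pass, although members moved both ways. Higher in B16-OVA were Lgals9 (1.42), Csf1 (0.78), Cdkn1a (0.62), Zmat3 (0.61), Trp53inp1 (0.52), Col1a1 (1.72), Thbs1 (1.46), Col5a1 (0.84), Pdk1 (0.65), Egln3 (0.58), Ddit4 (1.06), Chac1 (0.82), Trib3 (0.81) and Hsph1 (0.42). Lower were Nectin2 (-1.07), Tgfb1 (-0.93), Nfkbie (-0.85), Relb (-0.48), Bnip3 (-0.83) and Ier2 (-0.72), and Hspb1 was at 1.53 ± 0.143 RPKM in B16-WT and listed at 0 in both B16-OVA libraries. In all 2512 genes were higher and 2528 lower, 94 and 91 of them at least 2-fold. With median-of-ratios scaling 2570 were higher and 2416 lower. The calls of Xaf1 and Ifit3 (0.32 and -0.27 without B16-WT 0h replicate 1, 0.30 and -0.33 without B16-WT 0h replicate 2, 0.20 and -0.20 without B16-OVA 0h replicate 2) were lost in those settings. So was that of the class I list (adjusted p = 0.073 without B16-WT 0h replicate 2 and 0.079 without B16-OVA 0h replicate 2, and 0.11 with T cell RNA subtracted).

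At 6 h the comparison of B16-OVA with B16-WT was led by interferon-gamma target genes. Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29362107 to 29388095, GRCm38.p6), stood at 16.9 ± 0.744 RPKM in B16-OVA against 0.533 ± 0.109 (3.55 ± 0.13, adjusted p = 2.15e-08). Cxcl10, a chemokine that attracts CXCR3+ T cells, was at 281 ± 0.757 against 29.3 ± 0.317 (3.22 ± 0.07, adjusted p = 5.43e-10). The GTPase genes Gbp2 (6.82), Igtp (6.80), Irgm2 (5.95) and Irgm1 (5.58) and the transcription factor Irf1 (4.81) were among the largest rises. Prg4 (-4.57), Gpr137c (-3.48), Oca2 (-3.06), Trpm1 (-2.08) and Hgsnat (-1.99), all lower at 0 h as well, remained among the largest falls, and Spp1, the gene of osteopontin, was higher (4.17 ± 0.11, adjusted p = 9.17e-10).

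Of 30 interferon-gamma response genes, 29 were higher and 0 lower (29 and 1 adjusted over the list alone; adjusted p = 4.9e-27, and 0.00035 with an estimated correlation). Of 23 type I interferon response genes 18 were higher and 0 lower (19 and 0 adjusted over the list alone; adjusted p = 5.4e-10, and 0.0074 with an estimated correlation). Rtp4 was at 2.68, Stat2 at 2.62 and Xaf1 at 2.61. Class I presentation genes were higher in 19 of 21 cases and lower in 1 (adjusted p = 3.9e-09, and 0.012 with an estimated correlation). The peptide transporter Tap1 was at 3.14, Psmb10 at 2.52, Tapbpl at 2.36 and B2m at 0.72 (adjusted p = 3.75e-05). H2-K1 was 28.4 ± 0.18 against 16.9 ± 0.622 RPKM (0.71, adjusted p = 2.18e-05), in libraries whose T cell share was 3.375% and 1.457%. With T cell RNA subtracted it was 1.44 ± 0.25 against 6.42 ± 1.9 RPKM (-1.59). Psmb8, another class I presentation gene, went from 8.7 against 4.22 RPKM to 0.0 against 0.234 with subtraction. B2m stayed higher, at 232 against 152 RPKM, so the count of 19 may in part reflect carried T cell RNA. Both measured class II genes, Cd74 and Ctss, were higher, and with 2 of 9 measured the list was not tested. NF-kB and TNF response genes were higher in 8 of 15 cases and lower in 1 (adjusted p = 0.0046, and 0.11 with an estimated correlation). The macrophage growth factor Csf1 was at 3.27, Bcl3 at 1.44 and Tnfaip2 at 0.89. Dedifferentiation and mesenchymal genes were higher in 9 of 15 cases and lower in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.00055, and 0.089 with an estimated correlation). The matrix protein Thbs1 was at 3.41 and Col1a1 at 1.80. Melanocyte differentiation genes were lower in 16 of 22 cases and higher in 2 (18 and 2 adjusted over the list alone; adjusted p = 4.4e-05, and 0.014 with an estimated correlation). Kit was higher at 1.09, and Pmel was at -0.19 (adjusted p = 0.00273), a call lost with only the groups compared (-0.19). S phase genes were lower in 14 of 22 cases (15 adjusted over the list alone; adjusted p = 6.7e-05, and 0.014 with an estimated correlation). Uhrf1 was at -0.77, Lig1 at -0.71 and Mcm7 at -0.55.

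The other lists did not pass at 6 h. Of 9 checkpoint ligand genes 6 were higher and 2 lower (adjusted p = 0.057), with Lgals9 at 2.43, Tnfrsf14 at 1.5 and Serpinb9, an inhibitor of granzyme B, at 1.48. Of 24 p53 and cell death genes 9 were higher and 2 lower (adjusted p = 0.086), with the necroptosis effector Mlkl at 1.00, Casp4 at 0.79 and Gsdmd at 0.70. The unfolded protein and integrated stress response list had 13 of 21 higher and 4 lower (adjusted p = 0.05), with Slc7a11 at 1.93, Trib3 at 1.10 and Atf3 at 1.03. Mitotic genes went both ways, 10 higher and 4 lower of 22 (adjusted p = 0.3), with Cenpe at 0.55, Nusap1 at 0.53, Aurka at 0.51 and Mki67 at -0.50 (adjusted p = 7.47e-06). Glycolysis and hypoxia genes had 11 of 22 higher and 3 lower (adjusted p = 0.086), with Egln3 at 1.03, Hk1 at 0.79 and Pdk1 at 0.78. In cholesterol biosynthesis 9 of 20 were higher and 4 lower (adjusted p = 0.6), with Acat2 at -0.94 and Dhcr7 at -0.76. Heat shock genes had 6 of 16 higher and 5 lower (adjusted p = 0.91), with Zfp36 at 1.30, Junb at 0.76 and Hspb1 at -1.23. Actin and motility genes had 13 of 39 higher and 11 lower (adjusted p = 0.8), with Ezr at -0.68 and Vasp at -0.61. Tagln2, abundant in T cells, was higher by 0.80 (adjusted p = 0.00447) and lower by 0.37 once T cell RNA was subtracted. In all 3191 genes were higher and 2625 lower, 271 and 72 of them at least 2-fold. With 1 library left out 3 of these lists passed: checkpoint ligands without B16-OVA 6h replicate 2 (adjusted p = 0.041), glycolysis and hypoxia without B16-WT 6h replicate 2 (0.027), and the unfolded protein list without B16-WT 6h replicate 2 (0.029) or B16-OVA 6h replicate 1 (0.048). The unfolded protein list also passed with a pseudocount of 0.1 (0.046) and with T cell RNA subtracted (0.029).

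At 12 h the interferon-inducible genes were again higher in B16-OVA than in B16-WT. Cd274 was at 41.4 ± 0.0471 RPKM against 0.887 ± 0.449 in B16-WT (4.51 ± 0.13, adjusted p = 1.42e-09) and Cxcl10 at 1621 ± 10.6 against 47.0 ± 1.76 (5.08 ± 0.07, adjusted p = 6.3e-12). Gbp2 rose to 1062 ± 28.3 against 1.61 ± 0.0429 RPKM (8.67 ± 0.06, adjusted p = 8.98e-14), and the CXCR3 ligand Cxcl9 to 88.8 ± 4.19 against 0.0191 ± 0.027 (6.46 ± 0.07, adjusted p = 9.85e-13). B2m, the light chain of class I molecules, was at 687 ± 25.3 against 193 ± 4.77 RPKM (1.83 ± 0.08, adjusted p = 2.28e-08). The immediate early genes Fosb (1.41 ± 0.179 against 122 ± 2.24 RPKM, -5.68 ± 0.07, adjusted p = 2.37e-12), Fos (8.74 ± 0.396 against 150 ± 0.179 RPKM, -3.95 ± 0.08, adjusted p = 6.55e-11) and Jun (-3.10) were lower in B16-OVA.

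At 12 h 29 of 30 interferon-gamma response genes were higher and 0 lower (adjusted p = 5.4e-31, and 0.00028 with an estimated correlation), including Igtp (7.60), Iigp1 (7.39) and Irgm1 (5.55), beside Apol6 (5.55) and Batf2 (5.06) outside the list. All 23 type I interferon response genes were higher (adjusted p = 1e-20, and 0.0021 with an estimated correlation). Zbp1 was at 5.11, Ifit3 at 4.21 and Rtp4 at 4.20. Class I presentation genes were higher in 17 of 21 cases and lower in 0 (adjusted p = 4.5e-11, and 0.0074 with an estimated correlation), with Tap1 at 4.73, Psmb10 at 3.70 and Tapbpl at 3.6. H2-K1 did not pass (0.15, adjusted p = 0.0917; 25.5 ± 1.55 against 22.9 ± 1.9 RPKM, and 11.5 ± 0.077 against 7.79 ± 2.6 with T cell RNA subtracted). Of the class II genes Cd74 was higher over all genes, and Ctss when adjusted over the list alone. Checkpoint ligands were higher in 6 of 9 cases and lower in 2 (6 and 3 adjusted over the list alone; adjusted p = 0.011, and 0.067 with an estimated correlation). Lgals9 was at 2.36, Serpinb9 at 2.27 and Tnfrsf14 at 2.06. NF-kB and TNF response genes were higher in 12 of 15 cases and lower in 1 (12 and 2 adjusted over the list alone; adjusted p = 2.3e-06, and 0.027 with an estimated correlation). Csf1 was at 3.09, Bcl3 at 2.52 and Ccl5 at 2.42. Genes of p53 and cell death were higher in 18 of 24 cases and lower in 1 (19 and 1 adjusted over the list alone; adjusted p = 2e-07, and 0.014 with an estimated correlation). The inflammatory caspase Casp4 was at 3.11, Mlkl at 1.83 and the cell cycle inhibitor Cdkn1a at 1.57.

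Melanocyte differentiation genes were lower at 12 h in 17 of 22 cases and higher in 3 (adjusted p = 2.1e-05, and 0.013 with an estimated correlation), with Oca2 at -2.75, Trpm1 at -2.10 and Met at -1.21. Pmel was at -0.12 (adjusted p = 0.0218), a call lost with median-of-ratios scaling (-0.07) and without the filter or the variance trend (-0.12 each). Dedifferentiation and mesenchymal genes were higher in 9 of 15 cases and lower in 4 (adjusted p = 0.0058, and 0.15 with an estimated correlation). Thbs1 was at 4.14 and the fibronectin gene Fn1 at 2.29. S phase genes were lower in 18 of 22 cases (adjusted p = 4.5e-05, and 0.014 with an estimated correlation), with Uhrf1 at -0.71, Lig1 at -0.65 and Rrm1 at -0.62. Mitotic genes were lower in 15 of 22 cases and higher in 1 (15 and 2 adjusted over the list alone; adjusted p = 0.0029, and 0.13 with an estimated correlation). Mki67 (-0.95, adjusted p = 3.26e-08), Kif11 (-0.63) and Birc5 (-0.61) were among them. Cholesterol biosynthesis genes were higher in 13 of 20 cases and lower in 4 (adjusted p = 0.00055, and 0.027 with an estimated correlation). Lss was at 0.82, Hmgcs1 at 0.81 and Cyp51 at 0.78. Unfolded protein and integrated stress response genes were higher in 12 of 21 cases and lower in 3 (adjusted p = 0.0058, and 0.043 with an estimated correlation). Slc7a11 was at 1.60, Chac1 at 1.59 and Trib3 at 1.58. Glycolysis and hypoxia genes were higher in 15 of 22 cases and lower in 5 (adjusted p = 0.0058, and 0.23 with an estimated correlation). Hk2 was at 1.33, Pdk1 at 0.81 and Pfkl at 0.69. The actin list did not pass (14 higher and 13 lower of 39, adjusted p = 0.63), with Ezr at -0.88, Rhob at -0.88 and Rhoc at 0.86. The heat shock list did not pass either (6 and 5 of 16, adjusted p = 0.57), with Jund at -1.5. Prg4 (-4.59) and Gpr137c (-3.98) stayed low in B16-OVA, and 8 of 13 mitochondrially encoded transcripts were lower (median -0.57). In all 2903 genes were higher and 3604 lower, 417 and 125 of them at least 2-fold. With median-of-ratios scaling 3340 were higher and 2999 lower. H2-K1 passed without B16-WT 12h replicate 2 (0.23), with scaling (0.20) and with T cell RNA subtracted (0.54), and Pmel lost its call without that library or B16-OVA 12h replicate 2 (-0.10 for each).

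**Figure D2:**
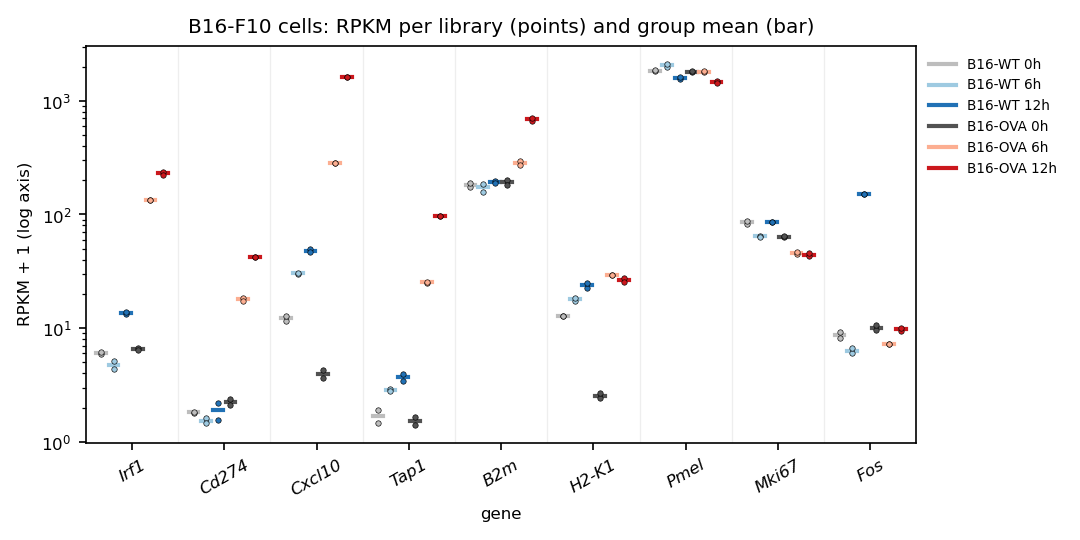
RPKM + 1 on a log axis for 9 genes in B16-WT and B16-OVA cells at 0, 6 and 12 h; points are single libraries and bars group means (n = 2). Cxcl10 went from 2.98 to 1621 RPKM in B16-OVA and from 11.3 to 47.0 in B16-WT, and Fos reached 150 RPKM in B16-WT at 12 h.

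Within B16-WT, 6 and 12 h were compared with 0 h. The mitophagy receptor Bnip3, a hypoxia-inducible gene, fell from 65.4 ± 4 RPKM to 8.17 ± 0.116 at 6 h (-2.85 ± 0.08, adjusted p = 8.49e-09) and 8.84 ± 0.815 at 12 h. The stress genes Chac1 (-2.85 and -2.26) and Ddit4 (-2.25 and -2.58) fell with it, as did Trib3 at 6 h (-2.25) and the angiogenic factor Vegfa at 12 h (-1.99). Selenbp1 fell by 2.46 and 2.10. Id2, a target of bone morphogenetic protein signalling, rose at 6 h from 53.6 ± 0.87 to 317 ± 17.6 RPKM (2.54 ± 0.06, adjusted p = 2.6e-09), beside Abca12 (2.69), Smad9 (2.57), Lims2 (2.53) and Atoh8 (2.50). At 12 h Fosb (6.39), Fos (4.12), Id1 (3.62), Klf4 (3.6) and Tnnt2 (3.19) were among the largest rises outside genes abundant in T cells. Cxcl10 rose by 1.31 (adjusted p = 8.11e-07) and 1.97 (adjusted p = 3.72e-08). Cd274 (-0.25, adjusted p = 0.149 and 0.04, adjusted p = 0.848) and B2m (-0.08, adjusted p = 0.394 and 0.09, adjusted p = 0.361) did not pass. H2-K1 was higher by 0.48 (adjusted p = 0.000299) and 0.89 (adjusted p = 5.48e-06), and lower by 0.80 and 0.56 with T cell RNA subtracted. Pmel differed by 0.16 (adjusted p = 0.00694, a call lost without the filter and with only the groups compared, 0.16 each) and -0.21 (adjusted p = 0.00133), and Mki67 by -0.40 (adjusted p = 3.81e-05) at 6 h while it did not pass at 12 h (0.01, adjusted p = 0.828).

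Unfolded protein and integrated stress response genes were lower in B16-WT in 19 of 21 cases at both times, with 1 and 2 higher (adjusted p = 7.3e-08 and 5.2e-07, and 0.0069 and 0.0074 with an estimated correlation). Glycolysis and hypoxia genes were lower in 17 and 18 of 22 cases (adjusted over the list alone, 17 and 18; adjusted p = 5.9e-06 and 4e-07, and 0.087 and 0.067 with an estimated correlation). Cholesterol biosynthesis genes were higher in 18 of 20 cases at 6 h (19 adjusted over the list alone; adjusted p = 1.9e-10, and 0.0044 with an estimated correlation). At 12 h 10 were higher (11 adjusted over the list alone; adjusted p = 0.022, and 0.087 with an estimated correlation). Interferon-gamma response genes were higher in 17 of 30 cases and lower in 1 at 12 h (adjusted p = 3.3e-07, and 0.0069 with an estimated correlation). At 6 h 8 were higher and 3 lower, and the list passed only with a pseudocount of 0.1 (adjusted p = 0.1, and 0.028 with it). Class I presentation genes were higher in 13 and 15 of 21 cases and lower in 3 (adjusted p = 0.00076 and 7.7e-06, and 0.056 and 0.023 with an estimated correlation). With T cell RNA subtracted the list did not pass at either time (adjusted p = 0.84, direction down, and 0.3). At 6 h 2385 genes were higher and 3572 lower, and with median-of-ratios scaling 3007 and 2878. At 12 h 2581 were higher and 3215 lower, and with that scaling 2994 and 2781. B2m was called lower at 6 h with T cell RNA subtracted (-0.26) and without B16-WT 6h replicate 1 (-0.20), and without B16-WT 12h replicate 1 Cd274 was called higher at 12 h (0.28).

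Within B16-OVA, interferon-gamma target genes rose strongly from 0 h. No B16 libraries are labelled as cultured alone at 6 or 12 h, so in both lines the change from 0 h cannot be split into co-culture and time in culture. Cd274 went from 1.24 ± 0.19 to 16.9 ± 0.744 and 41.4 ± 0.0471 RPKM, and Cxcl10 from 2.98 ± 0.484 to 281 ± 0.757 and 1621 ± 10.6. B2m rose by 0.56 (adjusted p = 0.000166) and 1.84 (adjusted p = 2.1e-08), Irgm1 by 4.77 and 5.35 and Irf1 by 4.34 and 5.12. Cxcl9, listed at 0 in both libraries at 0 h, reached 88.8 ± 4.19 RPKM at 12 h, when Apol6 had risen by 5.52. Tnnt2 (4.07) rose at 6 h. Chac1 (-3.07), Ddit4 (-2.81), Egr1 (-2.38) and Pck2 (-1.97) fell at 6 h, as did Ddit4 (-2.09) and Egr1 (-1.88) at 12 h. Mki67 fell by 0.48 and 0.53, and Pmel did not pass at 6 h (-0.01, adjusted p = 0.905) and fell by 0.31 (adjusted p = 8.2e-05) at 12 h. H2-K1 rose by 3.53 (adjusted p = 1.43e-10) and 3.38 (adjusted p = 8.51e-11), and with T cell RNA subtracted its 6 h difference was -0.06. Snord14e (-2.30) at 6 h and Snord14d (-1.81), Scarna9 (-1.99) and the mitochondrial ND4L (-1.99) at 12 h were called lower. The small RNA genes lie within host genes. Of 13 mitochondrially encoded transcripts 12 fell at 12 h (median -0.83).

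All 30 interferon-gamma response genes rose in B16-OVA at both times (adjusted p = 6.3e-31 and 2.6e-35, and 0.00028 with an estimated correlation at both). Of 23 type I interferon response genes 19 rose and 1 fell at 6 h (20 and 1 adjusted over the list alone; adjusted p = 1.1e-10, and 0.0071 with an estimated correlation). At 12 h 23 rose (adjusted p = 1e-21, and 0.002 with an estimated correlation). Class I presentation genes rose in 18 and 19 of 21 cases and fell in 2 and 0 (adjusted p = 2.2e-12 and 2.7e-16, and 0.0069 and 0.004 with an estimated correlation). At 6 h part of these rises may reflect carried T cell RNA, since Psmb8 was at 8.7 RPKM and at 0.0 with it subtracted. NF-kB and TNF response genes rose in 11 and 13 of 15 cases (adjusted p = 0.00065 and 2.7e-10, and 0.075 and 0.013 with an estimated correlation). Mitotic genes fell in 19 and 22 of 22 cases (adjusted p = 1.6e-05 and 1.1e-07, and 0.054 and 0.027 with an estimated correlation). Cholesterol biosynthesis genes rose in 15 and 11 of 20 cases and fell in 2 (15 and 13 rose adjusted over the list alone; adjusted p = 0.00021 and 0.00058, and 0.021 and 0.027 with an estimated correlation). Glycolysis and hypoxia genes fell in 17 and 15 of 22 cases and rose in 2 (18 and 16 fell adjusted over the list alone; adjusted p = 7.2e-05 and 0.0017, and 0.12 and 0.18 with an estimated correlation). At 6 h 2660 genes were higher and 3659 lower, or 3174 and 2993 with median-of-ratios scaling. At 12 h 2641 were higher and 4011 lower, or 3433 and 2995 with that scaling. The call of ND4L was lost without B16-OVA 0h replicate 1 (-1.21) or B16-OVA 12h replicate 2 (-1.39), and that of Scarna9 without B16-OVA 0h replicate 2 (-0.91), B16-OVA 12h replicate 1 (-2.34) or replicate 2 (-1.63).

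The change over time differed between the lines, as tested by the difference of the changes. At 6 h it was greater in B16-OVA for Irgm1 (4.94 ± 0.10, adjusted p = 4.84e-10), Cxcl10 (4.84 ± 0.10, adjusted p = 5.82e-10), Irf1 (4.70), the feedback inhibitor Socs3 (3.43), Cd274 (3.25) and B2m (0.64, adjusted p = 0.00358). At 12 h it was greater for Cxcl10 (6.71), Cxcl9 (6.46), Apol6 (5.51), Batf2 (5.09), Irgm1 (4.90), Cd274 (4.21), H2-K1 (2.49) and B2m (1.75). It was lower for Fosb (-6.06 ± 0.10, adjusted p = 4.95e-11), Fos (-4.17), Jun (-2.70), Klf4 (-2.65) and Mki67 (-0.54). Interferon-gamma response genes moved up in 28 and 29 of 30 cases (29 and 29 adjusted over the list alone; adjusted p = 1.8e-56 and 4.3e-53, and 0.00014 with an estimated correlation at both). Class I presentation genes moved up in 18 of 21 at both times (19 and 18 adjusted over the list alone; adjusted p = 4.5e-21 and 9.3e-21, and 0.0021 with an estimated correlation at both). Checkpoint ligands moved up in 5 and 7 of 9 cases (7 and 8 adjusted over the list alone; adjusted p = 5.2e-05 and 2.9e-07, and 0.016 and 0.0082 with an estimated correlation). Actin and motility genes moved up in 13 and 21 of 39, with 0 and 2 down (21 and 22 up, 1 and 2 down, adjusted over the list alone; adjusted p = 2.4e-05 and 2.7e-05, and 0.033 with an estimated correlation at both). Melanocyte differentiation genes moved down in 7 and 12 of 22 cases and up in 1 (13 and 13 down, 3 and 1 up, adjusted over the list alone; adjusted p = 0.0019 and 5.6e-05, and 0.029 and 0.014 with an estimated correlation). At 6 h this went with a rise in B16-WT, where 14 were higher and 6 lower (15 and 6 adjusted over the list alone; adjusted p = 0.0041, and 0.038 with an estimated correlation). In B16-OVA 11 were higher and 5 lower, and the list did not pass (adjusted p = 0.12), but it did with T cell RNA subtracted (adjusted p = 0.022). Mitotic genes moved down in 21 of 22 at 12 h (adjusted p = 2.6e-11, and 0.014 with an estimated correlation). At 6 h 3 moved down and 1 up (4 and 1 adjusted over the list alone; adjusted p = 0.0058, 0.15 with an estimated correlation and 0.055 without B16-WT 6h replicate 1). At 6 h 16 of 17 T cell markers moved up too, and H2-K1 went from 3.05 to 0.74 and lost its call with T cell RNA subtracted. At 6 h 949 genes moved up and 448 down, and at 12 h 1298 and 1328, or 1463 and 950 with median-of-ratios scaling. The 1397 calls at 6 h numbered 850 and 881 without B16-OVA 0h replicates 1 and 2, and 922 and 924 without B16-OVA 6h replicates 1 and 2. The 448 that moved down numbered 205, 226, 236 and 250 without these, in that order, and 233 without B16-WT 0h replicate 2. The 1328 at 12 h numbered 852 and 860 without B16-OVA 0h replicates 1 and 2.

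Transcripts of T cell genes in the B16 libraries stood at uneven shares of their level in T cells. In B16-OVA at 12 h the median of 11 cytokine and chemokine genes with far lower levels in B16 cells at 0 h than in T cells was 26.7% of the T cell level, with Il3 at 40.2%, Xcl1 at 31.3% and Ifng at 29.3% but Tnf at 2.9%. The T cell markers had upper quartiles of 2.31 and 2.03% in the libraries. Genes induced by T cell receptor signalling had a median of 5.9%, with Crtam at 23.5%.

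**Figure D3:**
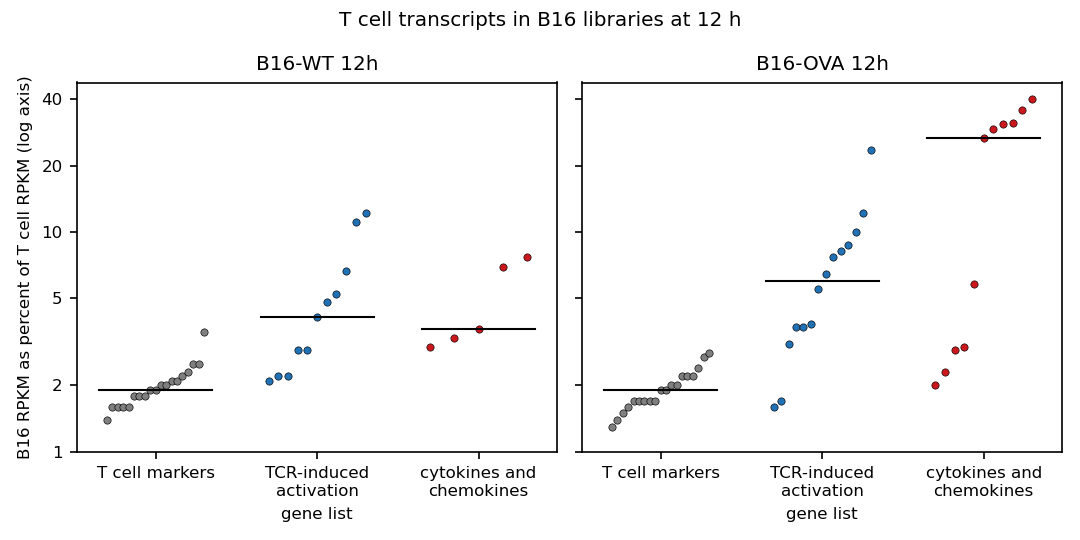
RPKM in B16-WT and B16-OVA libraries at 12 h as percent of the RPKM in T cells of the same co-culture, on a log axis, for T cell markers, genes induced by T cell receptor signalling and cytokines; points are genes (mean of 2 libraries) and lines medians. In B16-OVA the cytokine median was 26.7%.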

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

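The tests of H2-K1 below were chosen after its values had been seen; the tests of differences between changes were planned. Each result here was singled out because an effect differed between times or lines by a test of the difference itself.

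In T cells the antigen effect differed between 12 h and 6 h for 2522 genes, up for Egr1 (2.37), Il3 (2.34), Snord57 (2.17), Ccl3 (2.12), Snord110 (2.04), Ifng (1.47) and Gzmb (0.29), and down for Tnfrsf9 (-0.55), Sgol2a (-1.39), Ccng2 (-1.45), Cenpl (-1.59), Gzmc (-1.63) and Mir7669 (-1.64). Mir7669 lost its call without T with B16-WT 6h replicate 1 (-1.43), T with B16-OVA 6h replicate 2 (-1.46) or either T with B16-OVA 12h library (both -1.64). It also lost it without the filter (-1.64) and with voom (-1.96). The count was 1502 and 1581 without T with B16-WT 6h replicates 2 and 1, and 1574 and 1540 without T with B16-OVA 12h replicates 1 and 2.

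In B16 cells the 6 h change differed between B16-OVA and B16-WT for 1397 genes, up in B16-OVA for Irgm1 (4.94), Cxcl10 (4.84), Irf1 (4.70), Socs3 (3.43), Cd274 (3.25), H2-K1 (3.05) and B2m (0.64), and down for Abat (-0.97), Gamt (-0.98), Snord37 (-1.18), Isyna1 (-1.20) and Snora16a (-1.88). The count was 850, 881, 922 and 924 without B16-OVA 0h replicates 1 and 2 and 6h replicates 1 and 2. Snord37 lost its call without B16-WT 0h replicate 2 (-0.96), B16-WT 6h replicate 1 (-0.93), B16-OVA 0h replicate 2 (-1.0), or B16-OVA 6h replicate 1 (-1.26) or replicate 2 (-1.10), and Isyna1 (-0.35) and H2-K1 (0.74) lost theirs with T cell RNA subtracted.

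The 12 h change differed for 2626 genes, up in B16-OVA for Cxcl10 (6.71), Cxcl9 (6.46), Apol6 (5.51), Batf2 (5.09), Irgm1 (4.90), Cd274 (4.21), H2-K1 (2.49) and B2m (1.75), and down for Mki67 (-0.54), Mir24-2 (-2.38), Klf4 (-2.65), Jun (-2.70), Fos (-4.17) and Fosb (-6.06). Mir24-2 lost its call with a pseudocount of 0.1 (-4.19).

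H2-K1 was low in B16-OVA at 0 h (1.54 RPKM). With T cell RNA subtracted it was at 1.44 at 6 h and 11.5 at 12 h, so a rise at 6 h in the B16-OVA cells themselves is not shown. Reads moved between class I paralogs would leave their sum in place. Summed over 26 class I genes B16-OVA held 75.3 CPM against 143 in B16-WT, or 52.6%. This argues against such a move as the cause of the low level at 0 h. The sum cannot speak to reads left uncounted because they match several genes. Lower interferon signalling before co-culture would lower the interferon-gamma list, of which 1 of 30 members was lower (Cxcl10). At 0 h Cd274 stood at 0.816 RPKM in B16-WT and 1.24 in B16-OVA, and members this low can hardly be called lower. The count therefore does not decide this explanation. A difference between the lines that arose when B16-OVA was made stays open as an untested biological explanation.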

How the results depend on the processing

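The voom fit and the alternatives for the overlap of the antigen effects were chosen after the data had been seen. The overlap itself and the other alternatives were planned. Of 421 values of named genes, 418 kept their direction and their side of the threshold with a pseudocount of 0.1, 406 without the filter, 418 with median-of-ratios scaling, 405 with only the groups compared, 418 without the variance trend, 410 with the other cell type subtracted and 417 with voom; all 412 and 387 that could be tested did so with the filter at RPKM 5 and without genes abundant in the other cell type, as did 1817 of 1872 values with a library left out. Of 205 list tests, 202 did so with a pseudocount of 0.1, 201 with scaling, 196 with subtraction and 135 with an estimated correlation.

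Subtracting the other cell type changed the sign of 6 results. H2-K1 (-1.59) and Tagln2 (-0.37) did so in B16-OVA against B16-WT at 6 h. H2-K1 did so against 0 h in B16-WT at 6 h (-0.80) and 12 h (-0.56) and in B16-OVA at 6 h (-0.06). The class I list did so in B16-WT at 6 h against 0 h (adjusted p = 0.84). The value of -0.06 was near 0 and the list did not pass, so both are losses of an effect. By construction subtraction can over-remove genes abundant in T cells.

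With an estimated correlation 7 list tests passed in T cells and 55 in B16. The T cell comparison at 6 h gave 939 genes without the filter and 327 with only the groups compared, and the overlaps of the antigen effects were 237 and 144 higher and 152 and 47 lower; fewer libraries or more tested genes enter there by construction, and how much each weighed was not tested. With 1 library left out, the T cell counts were 395 to 2527 at 6 h (lowest without T with B16-WT 6h replicate 2, highest without T with B16-OVA 6h replicate 2; 498 without T with B16-WT 6h replicate 1), 2651 to 2926 at 12 h (2651 and 2719 without T with B16-OVA 12h replicate 1 and replicate 2) and 1502 to 3166 for the change of the antigen effect (1502 and 1581 without T with B16-WT 6h replicate 2 and replicate 1, 1574 and 1540 without T with B16-OVA 12h replicate 1 and replicate 2; its 1326 lower genes numbered 864 without T with B16-WT 12h replicate 2). The difference of the 6 h changes in B16 gave 850 to 1569 (850, 881, 922 and 924 without B16-OVA 0h replicate 1, 0h replicate 2, 6h replicate 1 and 6h replicate 2), and its 448 lower genes numbered 205, 226, 236 and 250 without these and 233 without B16-WT 0h replicate 2. The 1328 lower genes of the difference of the 12 h changes numbered 852 and 860 without B16-OVA 0h replicate 1 and replicate 2. The overlaps were 163 to 441 higher and 64 to 362 lower (163 and 64 without T with B16-WT 6h replicate 2, 180 and 86 without replicate 1), and the correlation of the effects 0.296 to 0.35; the cause was not tested for any of these.

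The mean over markers in place of the median moved the share of the other cell type to 0.054% in B16-WT at 0 h, 2.022% in B16-WT at 12 h, 0.040% and 3.306% in B16-OVA at 0 and 6 h, 0.489% in T cells at 0 h, 0.98% and 1.542% in T cells with B16-WT at 6 and 12 h, and 0.764% and 2.038% with B16-OVA; the cause was not tested. The replicate numbers did not pair the libraries (correlation of same-numbered deviations -0.03 to 0.09 over 10 pairs of groups in T cells and -0.19 to 0.14 over 15 in B16), and with the number as a block T cells with B16-OVA against B16-WT at 6 h gave 1598 genes and T cells with B16-OVA against B16-WT at 12 h gave 4211, with 421 of 421 named values and 204 of 205 list tests on the same side; the class I list at 0 h was at adjusted p = 0.052. At 29.32 to 37.0 M reads, depth limits mainly genes near RPKM 1 and small RNA genes.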

Other observations

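The list of transforming growth factor beta targets, the split of the cytokines and the genes named in the first 2 paragraphs were chosen after values had been seen, as were the tests of the average T cell profile and of expression by B16-OVA cells; the tests of antigen-engaged T cells, of B16 RNA in T cells and of unseen list members were written before their results.

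In both B16 lines Id1, Id3 and Smad6, genes known to respond to bone morphogenetic proteins, were higher at 6 and 12 h than at 0 h; targets of this pathway were not tested as a list. Id1 stood at 1.70, 14.1 and 32.1 RPKM in B16-WT at 0, 6 and 12 h and at 3.19, 41.7 and 53.5 in B16-OVA, and Id3 at 44.8, 252 and 312 and at 25.4, 316 and 312. Smad6, an inhibitor of that pathway, rose by 2.22 and 2.62 in B16-WT at 6 and 12 h and by 2.6 and 2.09 in B16-OVA. Spp1 was at 0.62, 0.74 and 0.93 RPKM in B16-WT and at 10.1, 30.2 and 47.1 in B16-OVA.

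In B16-WT at 12 h Fos (150 RPKM), Fosb (122), Jun (307) and Klf4 (22.7) were high, whereas Egr1 (12.2) and Ier2 (22.4) were lower than at 0 h. Epcam, whose protein the sort of cancer cells used, was at 0 to 0.222 RPKM in the B16 groups and at 1.09 to 3.74 in the T cell groups. Gapdh was at 84.8 ± 44.7 RPKM in T cells at 0 h and 9.01 ± 0.35 with B16-WT at 6 h.

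In T cells with B16-WT at 12 h, targets of transforming growth factor beta were higher than at 0 h: Cdh1 by 4.90, Itgae, the partner of E-cadherin, by 2.76, Skil by 2.70, Nt5e by 2.41, Pmepa1 and Ldlrad4 by 2.25 each, Lrrc32 by 1.92 and Foxp3 by 1.70. RNA of B16 cells would go with subtraction, but 15 of 15 called members remained called, which argues against it. If the T cells responded to this factor, members not looked at before should be higher too, and of 10 such members 7 were higher and 0 lower: Tgif1 (1.57), Smurf2 (1.46), Ski (1.45), Smad7 (1.39), Rgs16 (1.24), Tgif2 (0.86) and Smurf1 (0.57), while Tsc22d1 (0.09), Smad3 (-0.12) and Tgfbr1 (-0.03) did not pass. Of all 11066 genes 3035 were higher. At 6 h Smad3 was lower (-0.88, adjusted p = 9.62e-06). Such a response is a candidate explanation, and a change of medium or time in culture stays open, since T cells alone were sampled at 0 h only. Bambi was too low to test.

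Transcripts of T cell cytokines were high in the B16-OVA libraries at 12 h, at a median of 26.7% of the T cell level, above the upper quartiles of 2.31 and 2.03% over T cell markers, so T cells of average profile mixed into the sort cannot account for them. If antigen-engaged T cells were over-represented among those carried along, other genes of T cell receptor signalling should stand above the markers. Their median was 5.9%. B16-WT at 12 h gave 4.23 and 3.95% against upper quartiles of 2.25 and 2.18%, so part of this may not depend on antigen. Levels of these genes in B16 cells themselves were not subtracted and can raise the shares, so this median does not decide the question. If B16-OVA cells expressed single cytokine genes, the shares should be uneven, and the highest was 20.2 times the lowest, but engaged T cells with uneven induction would give this too, so both stay open. Shares of the 7 genes at least 2-fold higher in T cells with B16-OVA were 2 to 40.2% (Il3 40.2%, Ccl1 35.9%, Xcl1 31.3%, Ccl4 30.9%, Ifng 29.3%, Ccl3 26.7%, Il10 2.0%) and of the other 4 were 2.3 to 5.8% (Lta 2.3%, Tnf 2.9%, Tnfsf8 3.0%, Tnfsf11 5.8%). At 6 h Ccl1 was at 124.4% and Ifng at 61.7%.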
